A study of Homo sapiens with 84 samples.

How the data were processed

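The series profiled histone marks by CUT&RUN, in which an antibody directs a nuclease to the chromatin that carries a mark and the released fragments are sequenced. Of its 84 samples, 34 came with a list of broad peaks and were used: 18 libraries of H3K36me3 and 16 of H3K4me3, all from HEK293, a human embryonic kidney cell line. The titles of H3K36me3 replicates 1 to 3 at both temperatures without knockdown write HEK293WT and those of all other samples used write HEK293. These 6 H3K36me3 samples are the ones whose lists are named wt, while H3K4me3 lists named wt belong to samples titled HEK293. The other 50 samples (other marks, IgG controls and neural progenitor cells) were not analysed here because no peak list for them was used. Per the labels' protocols, 300000 cells per sample were permeabilised with 0.01% digitonin and 0.2 ng of E. coli DNA was spiked in. Cells were held at 32°C for 6 h or kept at 37°C, and for knockdown the temperature shift followed siRNA transfection by 48 h.

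Per the submitters' processing notes, Trim Galore 0.6.7, Bowtie2 2.4.4, SAMtools 1.15, MACS3, SEACR 1.3, bedtools 2.3, deepTools 3.5.1, DiffBind 3.9.6 and ChIPseeker 1.35.3 were among the tools and hg38 was the genome build. Which tool made which file is not given in the sources used here, and the list format is that of MACS broad peaks. Each deposited list belongs to 1 library, so peaks were called per sample and replicates could be compared. In these lists the authors give each peak a position, an integer score, a fold enrichment (a linear ratio), and the −log10 of a p-value and of a q-value. The score and fold are the authors' own values for each peak and were used only to describe, rank or filter peaks within a list. The names of the lists refer to IgG and to a q of 0.05, and the smallest deposited −log10 q was 1.30. Whether spike-in scaling entered the peak calls is not given in the sources used here. The deposited lists hold no read counts, so the sequencing depth of each library is unknown, and no interval for counting error could be given. Some samples were sequenced on a different instrument from others, per the series description, and which ones is not given. In all the lists hold 6429442 peaks, of which 55120 on other contigs were left out. The smallest gap between peaks was 81 bp in the H3K36me3 lists and 1201 bp in the H3K4me3 lists, so peaks closer than that form 1 peak and coverage and length do not mean the same for the marks. Of the promoter values tested for H3K4me3, 35.5% were 0 and 15.6% were full coverage, against 4.82% and 0.0287% of the H3K36me3 gene body values.

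Groups were taken from the sample labels. Lists with the word wt in their name were treated as one batch and lists named for an siRNA (negative control or SMYD5) as the other, because every knockdown list carries an siRNA name while the groups without SMYD5-KD in the label hold both kinds. From each list the genome length inside peaks, in Mb, was computed. For each of 19970 protein-coding genes on chromosomes 1 to 22 and X, the percent coverage of its gene body by the deposited H3K36me3 peaks was also computed, and likewise that of a promoter window by H3K4me3 peaks. Genes came from a RefSeq table of GRCh38.p14 with 59792 entries, the same build as the lists. The table gives no strand, so the promoter window (1000 bp on each side) was centred on the gene end with the higher mean H3K4me3 coverage over all 16 libraries. That departs from the planned annotated 5′ end. It was clear by 5 points or more for 13147 genes and not for 6823. As a check, 5976 genes of at least 10000 bp with a clear end and a mean H3K36me3 coverage of at least 5% were examined. Of these, 71.0% had more H3K36me3 in the part of the gene away from the chosen end (mean coverage 28.03% against 21.2%). The 6823 genes without a clear end were not checked.

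Coverage was compared with limma 3.58.1 in R 4.3.3, using 1 fit per mark over its 4 groups with terms for batch and for the log2 covered length of the library, empirical Bayes moderation with a trend and robust settings, and genes with a mean coverage of at least 5%. The residual degrees of freedom were 12 for H3K36me3 and 10 for H3K4me3. A gene was said to rise or fall only with a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Where a gene is said to rise or fall adjusted over a list alone, the adjustment covers only that list in a single comparison. It does not correct for the number of lists and comparisons. Differences are in percentage points of coverage, adjusted for batch and covered length, and can differ in sign from the plain group means. There were 5 comparisons per mark: 32°C against 37°C without SMYD5 targeted, the same in SMYD5-KD cells, knockdown against not targeted at 37°C, the same at 32°C, and the difference between the temperature effects (the interaction). Of 21 gene lists, those with at least 5 tested genes were tested with camera in limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over all lists and comparisons of a mark. Older symbols were matched through the synonyms of the RefSeq table. All members matched except 1 each of the circadian clock, interferon-response and pluripotency marker lists. Covered length and the location of peaks were compared with two-sided exact permutation tests in SciPy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, with plots from matplotlib 3.10.9).

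The design, the gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. By that rule SMYD5, SP1, CIRBP and RBM3 were always named, with the 10 largest rises and 10 largest falls among genes that passed. Where fewer than 5 genes passed, the 3 genes with the smallest unadjusted p in each direction were named as not passing. For each list called by camera, the 4 members with the smallest p in its direction were named. Other list members were named after their values were seen. Genes whose tested windows overlap are named together. A few results that the rule selects are not reported here.

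Alternatives covered the batch and covered-length terms, quantile normalisation, lists shortened to equal covered length, a log2(percent + 1) scale, a stricter −log10 q of 3, no filter on mean coverage, another window, siRNA-named lists alone, replicate blocks and leaving out each library. Array quality weights, a block by list-name number within batch, leaving out the 2 H3K36me3 libraries least correlated with the others, averaging both gene ends and fits within 1 list number were added after seeing the data. Fits within 1 list number were kept only for the temperature comparison without knockdown, because SMYD5-KD has 1 library per temperature there; their results for SMYD5-KD are not reported.

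Whether replicate numbers pair the libraries was checked from the correlation of their deviations from the group means, with pairing accepted where every pair was over 0.1. By label number this held for H3K4me3 in the temperature comparisons (0.216 to 0.517 over 5 pairs without knockdown and 0.175 to 0.447 over 3 pairs in SMYD5-KD). By the number in the list names it also held for H3K4me3 in the knockdown comparisons (0.204 to 0.388 at 37°C and 0.187 to 0.382 at 32°C). The H3K4me3 libraries that correlated best with their own number were 3 of 5 for temperature without knockdown and 3 of 3 in SMYD5-KD. For knockdown they were 1 of 3 at each temperature, so pairing there is weakly supported.

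The procedure was tested on simulated data made from these libraries with 200 genes changed by a known amount. Simulated values were not held within the possible range of coverage. The changes can thus include ones that real coverage cannot show, and the shares called are a rough guide. For the H3K36me3 temperature comparison over 7924 genes, 19.4% of changes of 10 points, 52.8% of 20 points and 75.7% of 30 points were called. For H3K36me3 knockdown at 37°C the shares were 9.4%, 41.8% and 60.4%. For H3K4me3 over 14230 promoters they were 4.1%, 0.1% and 0.8% in the temperature comparison and 0%, 0% and 5.7% for knockdown at 37°C. All these shares are means of 5 runs. Single H3K4me3 runs at 30 points gave 0% to 2.5% and 0% to 27.5%. Up to 2457 unchanged promoters were called in 1 H3K4me3 run. For H3K36me3 up to 7 unchanged genes were called in 1 run of the temperature comparison and up to 149 for knockdown at 37°C. With the preset correlation, camera called 64 of 450 unchanged list comparisons for H3K36me3 and 28 of 525 for H3K4me3; with an estimated correlation it called 0 and 6. A list of 40 genes raised by 10 points was called in 5 of 5 runs with the preset and 4 of 5 with the estimated correlation for H3K36me3, and in 3 of 5 and 0 of 5 for H3K4me3. The raised genes were drawn at random. The members of the gene lists vary together, with an estimated H3K36me3 correlation of 0.850 for splicing factor genes. These runs thus do not show that camera with an estimated correlation could call such lists.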

Results

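CUT&RUN peak lists of H3K36me3, a mark of transcribed gene bodies, and H3K4me3, a mark of active promoters, were compared in HEK293 cells. The design crossed mild cooling (6 h at 32°C against 37°C) with siRNA knockdown (KD) of SMYD5, a SET and MYND domain protein that the series title names as a regulator of the mild hypothermia response. H3K36me3 was profiled in 6 libraries at each temperature without SMYD5 targeted and in 3 at each temperature in SMYD5-KD cells. H3K4me3 was profiled in 5 and 3. The H3K36me3 lists held 99280 to 349117 peaks covering 35.3 to 169 Mb, and the H3K4me3 lists held 50470 to 225692 peaks covering 20.7 to 167 Mb. Read depth is unknown. Nothing in the labels tells that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

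The gene body of SMYD5 (GRCh38 chromosome 2, 73214245 to 73227221) was covered by H3K36me3 peaks over 25.9% ± 17.6 (SD, n = 6) at 32°C and 10.3% ± 6.91 (n = 6) at 37°C where it was not targeted. In SMYD5-KD cells the values were 11.8% ± 5.93 (n = 3) at 32°C and 2.24% ± 2.11 (n = 3) at 37°C. After adjustment for batch and covered length the temperature difference without knockdown was 13.5 points (SE 4.28, limma adjusted p = 0.111), and in SMYD5-KD cells it was 6.72 points (SE 6.04), with an interaction of -6.81 points (SE 7.22). Without adjustment the plain means without knockdown differed by 24.2 points among lists named wt and by 7.14 among siRNA-named lists. The knockdown difference was 3.45 points (SE 5.70) at 37°C and -3.36 points (SE 5.63) at 32°C. None passed, and at 37°C the adjusted difference and the plain means have opposite signs. The SMYD5 promoter had H3K4me3 coverage of 22.1% ± 26.0 (n = 5) at 32°C and 44.4% ± 41.8 (n = 5) at 37°C (-25.7 points, SE 24.1, not passing). In SMYD5-KD cells it was 33.3% ± 57.7 and 44.3% ± 51.0 (n = 3 each; -17.5 points, SE 31.2), and the knockdown differences were 5.60 points (SE 29.4) at 37°C and 13.8 points (SE 29.5) at 32°C, none passing. Peak coverage of a gene does not measure its transcript, so it does not check the knockdown.

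H3K36me3 over SP1, CIRBP and RBM3 did not pass in any comparison. SP1 encodes a transcription factor, and CIRBP and RBM3 encode cold-inducible RNA-binding proteins. At 32°C against 37°C without knockdown SP1 differed by 2.08 points (SE 6.03), CIRBP by -5.92 (SE 8.13) and RBM3 by -4.12 (SE 7.48). CIRBP coverage was 37.9% ± 14.9 at 32°C and 37.7% ± 25.7 at 37°C (n = 6 each), and RBM3 coverage 38.2% ± 15.6 and 36.7% ± 22.7. In SMYD5-KD cells the temperature difference was 6.69 points (SE 11.5) for CIRBP and 8.60 points (SE 10.5) for RBM3.

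H3K36me3 peaks lay mostly in gene bodies, which held 77.2% ± 9.08 (SD, n = 18) of the covered length, with 22.01% ± 8.97 between genes and 0.743% ± 0.158 in promoter windows. H3K4me3 peaks held 10.7% ± 3.79 (n = 16) of their length in promoter windows, 46.5% ± 7.67 in gene bodies and 42.8% ± 10.2 between genes. The marks differ in the smallest gap between peaks (81 bp for H3K36me3, 1201 bp for H3K4me3), so these shares are not compared between them. Randomly placed peaks would give 1.21%, 40.9% and 57.9% for promoters, gene bodies and intergenic sequence. The promoter ends were chosen from these H3K4me3 lists, which favours the H3K4me3 promoter share over random placement. Of 24 two-sided exact permutation tests of these shares between groups, 0 passed (0 at unadjusted p under 0.05, smallest adjusted p = 1). The smallest possible exact p was 0.00216, with 6 libraries per group, so a single differing share could not pass over 24 tests. For temperature in SMYD5-KD cells (n = 3 each) it was 0.1, so those tests could not pass at all. There the gene body share differed by 7.17 points for H3K36me3 (exact p = 0.4) and 0.221 for H3K4me3. The tests thus do not show that the shares are equal.

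The length of genome inside H3K36me3 peaks was 128 ± 41.4 Mb (n = 6) at 32°C and 108 ± 36.1 Mb (n = 6) at 37°C without knockdown, a log2 difference of 0.25 (two-sided exact permutation p = 0.409). It was 0.59 among lists named wt (p = 0.1, n = 3 each, exact, the smallest p possible) and -0.09 among siRNA-named lists (exact p = 0.7), so the direction was not shared by the batches. In SMYD5-KD cells it was 85.7 ± 25.3 and 71.9 ± 32.0 Mb (log2 difference 0.34, exact p = 0.7, smallest possible 0.1, n = 3 each). Knockdown differences were -0.64 at 37°C (exact p = 0.214) and -0.55 at 32°C (exact p = 0.190). Among siRNA-named lists alone they were -0.55 (exact p = 0.4) and -0.12 (exact p = 0.8). The H3K4me3 lists covered 107 ± 62.1 Mb at 32°C and 88.4 ± 54.0 Mb at 37°C without knockdown (n = 5 each, log2 difference 0.19, exact p = 0.833; 0.13 among lists named wt and 0.23 among siRNA-named lists). In SMYD5-KD cells they covered 106 ± 61.4 and 87.3 ± 53.3 Mb (0.37, exact p = 0.7, n = 3). The H3K4me3 knockdown differences were -0.05 at 37°C (exact p = 0.857; 0.06 among siRNA-named lists) and 0.13 at 32°C (exact p = 0.964; 0.20 among siRNA-named lists). None of the 8 passed after adjustment (adjusted p from 0.857 to 0.964). The temperature effects with and without knockdown differed by 0.09 for H3K36me3 (permutation p = 0.880 over 7056 labellings) and 0.17 for H3K4me3 (permutation p = 0.881 over 3136).

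Leaving out 1 library turned the direction of several of these length differences. The H3K36me3 difference in SMYD5-KD cells became -0.11 without 37°C KD replicate 3. The H3K4me3 temperature difference became -0.03, -0.04, -0.01 and -0.12 without 32°C replicates 3 and 5 and 37°C replicates 2 and 4. In SMYD5-KD cells it became -0.06 and -0.34 without 32°C KD replicate 3 and 37°C KD replicate 2. The H3K4me3 knockdown difference at 37°C became 0.66, 0.24, 0.09 and 0.05 without KD replicate 2 and 37°C replicates 1, 3 and 5. At 32°C it became -0.30 and -0.38 without KD replicate 3 and 32°C replicate 4.

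**Figure D1:**
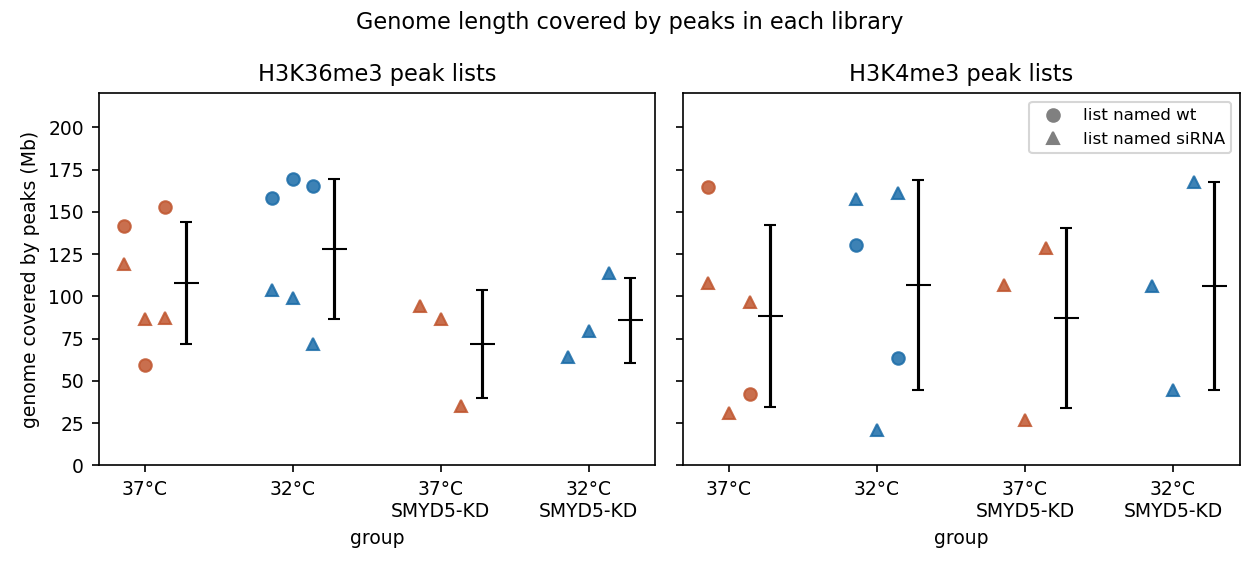
Genome length covered by peaks (Mb, vertical axis) in each library of H3K36me3 (left) and H3K4me3 (right), by group. Points are libraries (circles for lists named wt, triangles for siRNA-named lists) and black marks with bars are the mean and SD. The groups overlap, as for H3K36me3 at 32°C (128 ± 41.4 Mb) and 37°C (108 ± 36.1 Mb).

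The comparison of 32°C with 37°C asks which genes change their H3K36me3 in mild cold. ZSWIM1, a SWIM-type zinc finger gene (chromosome 20, 45880920 to 45885266), had no H3K36me3 peak in any of 6 libraries at 37°C and 43.5% ± 13.3 coverage (SD, n = 6) at 32°C, a fitted rise of 42.3 points (SE 4.82, adjusted p = 0.000255). COXFA4, which encodes a protein associated with cytochrome c oxidase (chromosome 7, 10931943 to 10940153), rose from 8.75% ± 11.7 to 53.3% ± 17.5 (39.2 points, SE 5.89, adjusted p = 0.00218). COPS8, a COP9 signalosome subunit (chromosome 2, 237085889 to 237100474), rose from 16.6% ± 11.5 to 57.5% ± 18.1 (37.2 points, SE 6.68, adjusted p = 0.0068). CCNA2, which encodes cyclin A2 (chromosome 4, 121816444 to 121823883, overlapping EXOSC9), fell from 64.3% ± 33.2 to 25.8% ± 14.8 (-43.0 points, SE 11.0, adjusted p = 0.0450). HMGN2, a nucleosome-binding protein gene (chromosome 1, 26472440 to 26476642), fell from 60.3% ± 25.1 to 28.4% ± 16.0 (-38.0 points, SE 9.88, adjusted p = 0.0466). Across 25 settings compared gene by gene, ZSWIM1 and COXFA4 kept their calls in 23 each and COPS8 in 21, but CCNA2 in 8 and HMGN2 in 10.

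Among the 7924 gene bodies tested, coverage rose over 147 and fell over 42 (limma, adjusted p under 0.05), and 1167 had an unadjusted p under 0.05. The rises had a median of 16.9 points, the falls a median of -20.1 points, and the median over all tested genes was 1.67 points with a median SE of 4.72. The other large rises were CIAO1, of cytosolic iron-sulfur assembly (35.4 points), NDUFAB1, the mitochondrial acyl carrier protein (35.2), GATD1 (34.9), RBM12B (34.0, overlapping CIBAR1), TIMM8B, a mitochondrial import chaperone (33.8, overlapping NKAPD1), RAE1, an mRNA export factor (33.5), and MRPS7, of the small mitochondrial ribosomal subunit (33.2, overlapping GGA3 and MIF4GD). The other large falls were MRPL20 (-36.4 points) and MRPL46 (-31.6) of the large mitochondrial ribosomal subunit, PDCD2 (-35.3), UNC50 (-33.5), CHCHD7 (-31.3) and ADPRS (-28.4). Of the 25 settings RAE1, MRPL46 and CHCHD7 kept their calls in 7 each and MRPL20 in 11, and the others of these genes in 16 to 22. How reads shared with near-identical copies were treated is not given in the sources used here, which leaves genes with processed copies, such as HMGN2, less certain.

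The count depended on the setting and on single libraries. It was 0 in siRNA-named lists alone, a fit that includes the SMYD5-KD libraries. Fits to only the libraries without knockdown of a single batch, with 3 residual degrees of freedom, called 152 genes among siRNA-named lists and 343 among lists named wt. The count was 57 without the batch term, 122 without the covered-length term, 27 without both and 58 on the log2 scale. It was 75 with no filter and 32 in promoter windows, but 572 (314 rises and 258 falls) after quantile normalisation. With stricter peaks it was 273, of which 133 rose and 140 fell, and in lists of equal covered length it was 156, of which 34 were among the 189. With array quality weights, added after seeing the data, it was 881 (496 rises and 385 falls), and without the 2 least correlated libraries, also added, 289 (134 and 155). Leaving out 37°C replicate 1 gave 62 genes, 37°C replicate 4 gave 82, 32°C replicate 1 gave 95 and 32°C replicate 3 gave 123. Without 37°C replicates 2 and 6 in turn it was 262 (147 rises and 115 falls) and 250 (139 and 111). The 189 genes had the same sign in both batches (100%), although they were chosen on both, with a median size of 14.3 points among siRNA-named lists and 18.2 points among lists named wt. All genes named above as rising or falling lost their call in siRNA-named lists alone and 0 of them changed sign in the settings compared gene by gene, which leave out the log2 scale and the promoter windows.

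**Figure D2:**
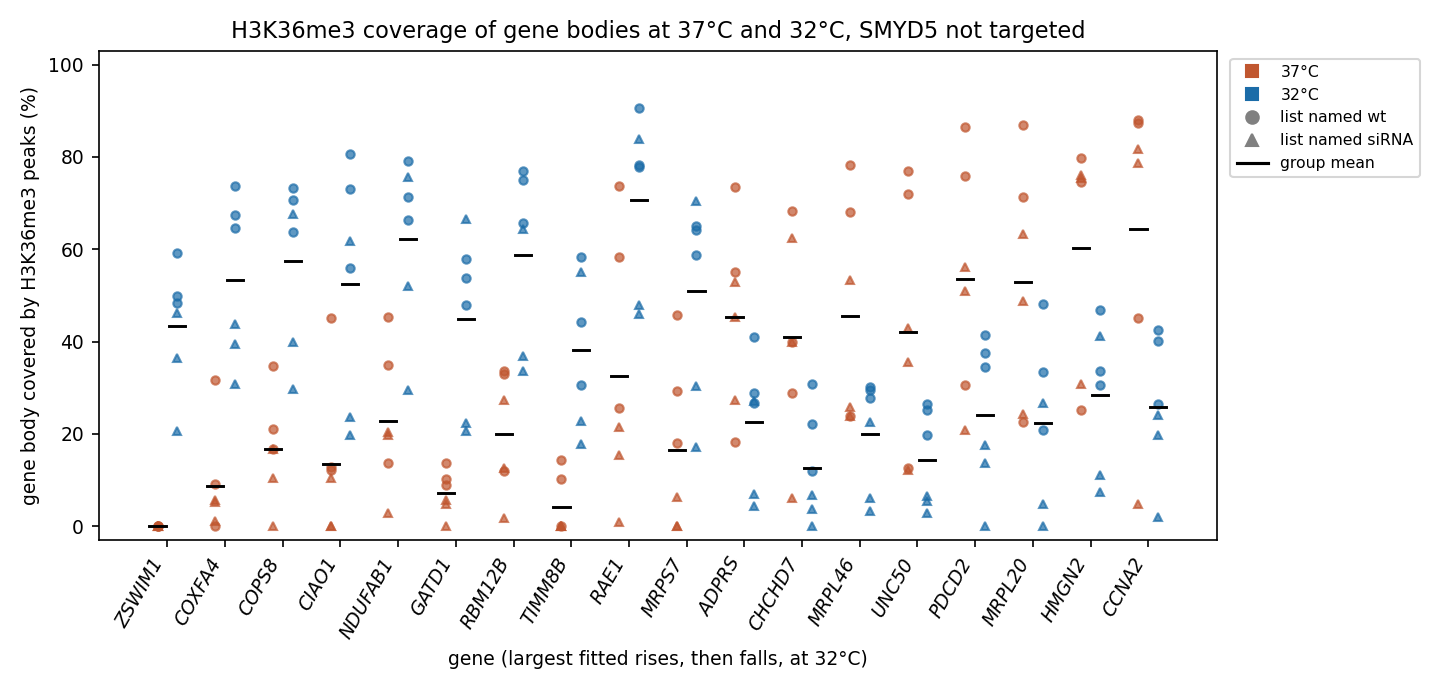
Percent of the gene body covered by H3K36me3 peaks (vertical axis) for the named genes with the largest fitted rises (left) and falls (right) at 32°C, SMYD5 not targeted. Points are libraries (n = 6 per temperature, circles for lists named wt, triangles for siRNA-named lists) and black lines are group means, such as 0% and 43.5% for ZSWIM1 at 37°C and 32°C.

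By gene group, 3 of 54 tested mitochondrial respiratory chain genes rose and 51 did not pass: COXFA4, NDUFV1 (29.7 points, SE 5.33) and ATP5F1C (23.1 points, SE 6.05). Adjusted over the list alone, 4 rose, with NDUFA12 (9.99 points) added. Of 330 numbered zinc finger (ZNF) genes, 14 rose, 3 fell and 313 did not pass; adjusted over the list alone, 16 rose and 7 fell. ZNF655 rose by 30.1 points (SE 5.17), ZNF613 by 19.7 (SE 2.58) and ZNF555 by 14.02 (SE 1.94), while ZNF416 fell by 26.6 (SE 6.58), ZNF691 fell by 24.5 (SE 5.97) and ZNF823 fell by 8.35 (SE 1.88). ZNF genes lie in clusters of similar sequence, which leaves single members uncertain. Among 32 widely expressed reference genes the glycolytic gene TPI1 rose (26.8 points, SE 5.71), 1 other fell and 30 did not pass (adjusted over the list alone, 1 rose and 1 fell). HSD17B7, of cholesterol synthesis, rose by 11.7 points (SE 2.33; 1 of 22 members, also 1 adjusted over the list alone). GINS3, of the replicative helicase complex, rose by 14.1 points (SE 3.15; 1 of 40 DNA replication genes, also 1 adjusted over the list alone). CCNA2 was the 1 of 38 mitotic cell cycle genes that fell, with 37 not passing, also 1 adjusted over the list alone. Apart from COXFA4 and CCNA2, these members were named after their values were seen.

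Of 14 H3K36 methylation enzyme genes 0 passed over all genes; adjusted over the list alone, SMYD5 (13.5 points, adjusted p = 0.0364) and SETMAR (11.4 points, adjusted p = 0.0357) did. Of 9 immediate early genes 0 passed over all genes, and adjusted over the list alone ATF3 fell by 4.52 points (SE 1.38). For the other lists 0 members passed, also 0 adjusted over the list alone: 8 cold-inducible, 22 heat shock and chaperone, 21 H3K4 methylation enzyme, 9 circadian clock, 76 cytosolic ribosomal protein, 35 splicing factor, 25 unfolded protein response, 22 p53 target, 7 interferon-response and 5 neural progenitor marker genes. The cold-inducible list had a median of -0.0492 points and a mean of -1.90. The heat shock list had a median of -0.195 and a mean of 1.56 points. As whole lists none of the 18 with enough tested genes was called by camera (smallest adjusted p = 0.0589, immediate early genes, downward relative to other genes). In 9 of the 18 the direction of that test differed in sign from the list's median or mean, since the median of all genes was above 0. Pluripotency, blood cell and olfactory receptor lists had too few genes with H3K36me3 coverage.

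The same temperature contrast in SMYD5-KD cells asks whether the cold response of H3K36me3 appears when SMYD5 is reduced. No gene passed. RPL7A, a ribosomal protein gene (chromosome 9, 133348218 to 133351426), had no H3K36me3 peak in the 3 KD libraries at 37°C and 72.5% ± 9.74 coverage (n = 3) at 32°C, a difference of 68.6 points (SE 14.2, adjusted p = 0.856). MRPL18, of the mitochondrial ribosome, differed by 49.7 points (59.2% ± 15.5 against 6.71% ± 6.19) and SLC46A1, a folate transporter gene, by 8.56 points (overlapping SARM1). HEY1, a Notch target gene, differed by -36.1 points, ACTB, which encodes beta-actin, by -32.8 and C8orf33 by -41.0. Neither HEY1 nor C8orf33 had a peak in the 3 KD libraries at 32°C. In limma 0 of 7924 genes passed, with 209 at an unadjusted p under 0.05.

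Among lists, camera called ribosomal protein genes (62 of 76 with a positive difference, median 6.74 points, adjusted p = 0.0490), splicing factors (31 of 35, median 10.0, adjusted p = 0.00478) and mitotic genes (33 of 38, median 7.45, adjusted p = 0.0123) as higher at 32°C in SMYD5-KD cells. For all 3 the call was lost: adjusted p = 0.997 with an estimated correlation. No member passed over all genes; adjusted over the list alone, RPL7A rose among ribosomal protein genes and 0 members did among splicing and mitotic genes. The splicing genes SRSF1, HNRNPK (overlapping RMI1), SNRNP70 and HNRNPU (overlapping LOC124904588) differed by 29.0, 40.3, 36.1 and 34.6 points. The mitotic genes MAD2L1, CCNA2 (overlapping EXOSC9), BIRC5 and CDC20 differed by 33.9, 37.0, 28.1 and 22.4 points. The ribosomal genes RPL35A (overlapping DRC9) and RPS15 differed by 41.8 and 17.7 points. Ribosomal protein genes and ACTB have many processed copies, so their values are uncertain. Outside the called lists, ACTB fell among reference genes adjusted over the list alone. The gene count became 148 after quantile normalisation, 98 on the log2 scale and 2092 with array quality weights.

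Knockdown at 37°C asks whether SMYD5 shapes H3K36me3 without cold. COXFA4 differed by 38.4 points between SMYD5-KD (29.1% ± 23.8, n = 3) and not targeted cells (8.75% ± 11.7, n = 6; SE 7.85, adjusted p = 0.470). SPATA2 and the mitochondrial carrier gene SLC25A27 differed by 11.9 and 10.1 points. RPL7A differed by -48.2 points (no peak in 3 KD libraries against 59.0% ± 27.1), MSRB1, a methionine sulfoxide reductase gene, by -12.2 and AGO4, an Argonaute gene, by -9.97. None passed in limma (0 of 7924 genes, 237 at an unadjusted p under 0.05).

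The p53 target list was called lower at 37°C after knockdown (5 of 22 members positive, median -2.97 points, camera adjusted p = 0.00185), and the call was lost: adjusted p = 0.997 with an estimated correlation. Its members BBC3, a cell death gene, CDKN1A, a cell cycle inhibitor gene, PLK2 and PLK3 (overlapping DYNLT4) differed by -11.8, -9.15, -15.1 and -7.39 points. Over all genes 0 members passed, and 0 adjusted over the list alone. Adjusted over their lists alone, DNAJB9 rose among unfolded protein response genes (28.05 points) and COXFA4 among respiratory chain genes. The gene count became 322 after quantile normalisation, 62 on the log2 scale and 1405 with array quality weights.

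Knockdown at 32°C asks the same in cold cells. PDCD2 differed by 55.4 points between SMYD5-KD (60.5% ± 9.95, n = 3) and not targeted cells (24.1% ± 16.2, n = 6; SE 10.1, adjusted p = 0.199). FIGNL1 differed by 48.8 points and ZNF574 (overlapping GRIK5) by 10.8. DCPH1 differed by -29.2 points (3.901% ± 1.74 against 42.7% ± 9.64), THAP12 by -11.8 and MMD by -8.63. None passed in limma (0 of 7924 genes, 488 at an unadjusted p under 0.05).

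At 32°C camera called ribosomal protein genes (57 of 76 positive, median 10.4 points, adjusted p = 0.00478), unfolded protein response genes (20 of 25, median 5.04, adjusted p = 0.0490) and mitotic genes (33 of 38, median 6.43, adjusted p = 0.0364) as higher in SMYD5-KD cells. Each call was lost: adjusted p = 0.997 with an estimated correlation. Among ribosomal genes RPL35A (overlapping DRC9) differed by 54.2 points, RPL29 by 42.5, RPL3 by 31.5 and RPS26 by 28.5. CALR, an endoplasmic reticulum chaperone gene, differed by 32.2 points, DDIT3 (overlapping MARS1 and LOC128125814) by 19.9, ASNS by 7.05 and ATF3 by 5.04. CCNA2 (overlapping EXOSC9) differed by 58.7 points, CDK1 by 31.7, CKAP2 by 18.8 and PRC1 by 17.9. No member of the called lists passed over all genes; adjusted over the list alone CCNA2 did among mitotic genes, and 0 did among ribosomal and unfolded protein response genes. Among reference genes 1 rose and 1, ACTB, fell adjusted over the list alone. The gene count became 181 after quantile normalisation, 60 on the log2 scale, 9 in siRNA-named lists alone and 664 with array quality weights.

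The interaction asks whether the temperature effect differs with knockdown. COXFA4 rose by 39.2 points in the cold without knockdown, whereas in SMYD5-KD cells its coverage was 24.0% ± 15.9 at 32°C and 29.1% ± 23.8 at 37°C (n = 3 each; interaction -51.6 points, SE 9.93, adjusted p = 0.0940). ZNF112 and ZNF613 had interactions of -15.0 and -22.6 points (adjusted p = 0.0940 each). PRMT1, an arginine methyltransferase gene, had 42.0 points (SE 7.86, adjusted p = 0.0940), PDCD2 57.9 and MRPL58 34.0. In limma 0 of 7924 genes passed, with 491 at an unadjusted p under 0.05, so the 189 genes called without knockdown and the 0 called in SMYD5-KD cells are not shown to differ. CCNA2 coverage in SMYD5-KD cells was 69.4% ± 18.0 at 32°C and 26.3% ± 8.99 at 37°C (n = 3 each), against a fall without knockdown, and its interaction did not pass over all genes (adjusted p = 0.181).

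Ribosomal protein genes were called by camera in the interaction, with a more positive temperature effect in SMYD5-KD cells (52 of 76 positive, median 4.96 points, adjusted p = 0.0364), and the call was lost: adjusted p = 0.997 with an estimated correlation. RPL35A (77.2 points, overlapping DRC9) and RPL7A (65.3 points) passed adjusted over the list alone, and RPL23A (overlapping TLCD1) had 33.9 points. Adjusted over their lists alone, CCNA2 (80.0 points) was positive, COXFA4 and ACTB (-43.7) were negative, and of the ZNF genes 2 were positive (ZNF792 and ZNF574) and 3 negative (ZNF655, ZNF112 and ZNF613). The interaction count became 7 without 37°C replicate 6 and 1 without 37°C replicate 3. It was 243 after quantile normalisation, 83 on the log2 scale and 1099 with array quality weights.

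H3K4me3 promoter coverage did not pass for any of 14230 genes in any comparison (limma, 0 calls each). In the cold without knockdown, GLRX5, of mitochondrial iron-sulfur assembly, had full coverage (100%) in all 5 libraries at 32°C and 52.7% ± 43.6 (n = 5) at 37°C, a difference of 47.3 points (adjusted p = 1). NFYA (overlapping OARD1) and ISOC1 differed by 49.0 and 55.0 points. PLEKHA3, FCGR3B (uncertain, as it has near-identical copies) and BRCA1 differed by -58.2, -61.0 and -38.9 points, and BRCA1, a DNA repair gene, had 64.5% ± 38.5 at 32°C against 100% at 37°C. SP1, CIRBP and RBM3 differed by -6.67 (SE 22.9), 4.77 (SE 23.1) and -15.2 (SE 22.4) points. At an unadjusted p under 0.05 there were 189 genes, and the smallest adjusted p was 1.

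In SMYD5-KD cells, H3K4me3 at the promoters of TFB2M, a mitochondrial transcription factor gene, CNST and TIMM9 (overlapping TOMM20L and KIAA0586) was higher in the 32°C libraries by 87.0, 81.7 and 75.6 points without passing, and lower at LAMTOR2, UBQLN4 and RPS25 (overlapping CENATAC) by differences of -84.5, -90.0 and -62.9 (421 genes at unadjusted p under 0.05, smallest adjusted p = 0.176). For knockdown at 37°C GLRX5, THRAP3 and SHISA9 had differences of 63.1, 62.8 and 47.2 points, and NUDCD2 (overlapping CCNG1), HMMR and TIMM9 of -82.6, -81.8 and -67.7 (246 genes, smallest adjusted p = 0.305). At 32°C EIF5, ABCC2 and OR2F1 had 75.2, 57.6 and 55.5 points, and PCMTD1, RPS25 and TRAPPC4 (overlapping SLC37A4) -76.2, -71.5 and -56.2 (323 genes, smallest adjusted p = 0.145). For the interaction TFB2M, CNST and TIMM9 had 94.9, 93.6 and 85.2 points, and HBP1 (overlapping COG5), CATSPERE (overlapping ADSS2) and TM9SF3 -93.2, -92.0 and -86.7 (218 genes, smallest adjusted p = 0.974). None of these passed. The promoter windows of TFB2M and CNST, UBQLN4 and LAMTOR2, RPS25 and TRAPPC4, and NUDCD2 and HMMR overlap, so each such pair shares peaks.

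Of the 21 gene lists tested on H3K4me3, camera called 0 in any comparison, in a test that missed a simulated raised list in 2 of 5 runs. The smallest adjusted p was 0.0833, for 34 olfactory receptor genes in the temperature comparison of SMYD5-KD cells (median 0.795 points). Without knockdown, 6 pluripotency genes had a median temperature difference of 3.82 points, 8 blood cell marker genes -8.82 and 10 cold-inducible genes 5.31 (adjusted p = 0.973 each). The direction of the test differed in sign from the median or mean for 4, 11, 6, 7 and 10 lists in the order of comparisons above. Adjusted over the list alone, RPS25 and RPS2 fell and HNRNPA1 rose in the cold in SMYD5-KD cells. At 37°C RPL7A, HNRNPA1 and HMMR fell after knockdown. At 32°C HSPD1, HSPE1, RPS6, RPS25 and RPS2 fell and OR2F1 and OR9K2 rose, also only adjusted over the list alone. None of these members passed over all genes, and the adjustment over a list does not correct for the number of lists and comparisons. Members outside the rule were named after their values were seen.

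The H3K4me3 libraries split by the number in their list names more than by group. Mean promoter coverage was 42.9% to 56.6% in the 6 libraries numbered 1, 8.44% to 13.4% in the 4 numbered 2 and 16.0% to 24.2% in the 6 numbered 3, each number holding both temperatures and SMYD5-KD. With a block by list-name number, which met the rule for pairing, 0 genes passed in each comparison. A fit within number 1, added after seeing the data, gave 6 genes for cold without knockdown. On the log2 scale 22 genes passed for cold in SMYD5-KD cells and 25 for knockdown at 37°C; array quality weights gave 77 to 3125 calls. Leaving out 1 library gave 3 and 4 genes for cold in SMYD5-KD cells (without 32°C and 37°C KD replicate 1), 2 for knockdown at 37°C (without KD replicate 1 or 3), and 2 and 1 at 32°C (without KD replicates 1 and 2).

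**Figure D3:**
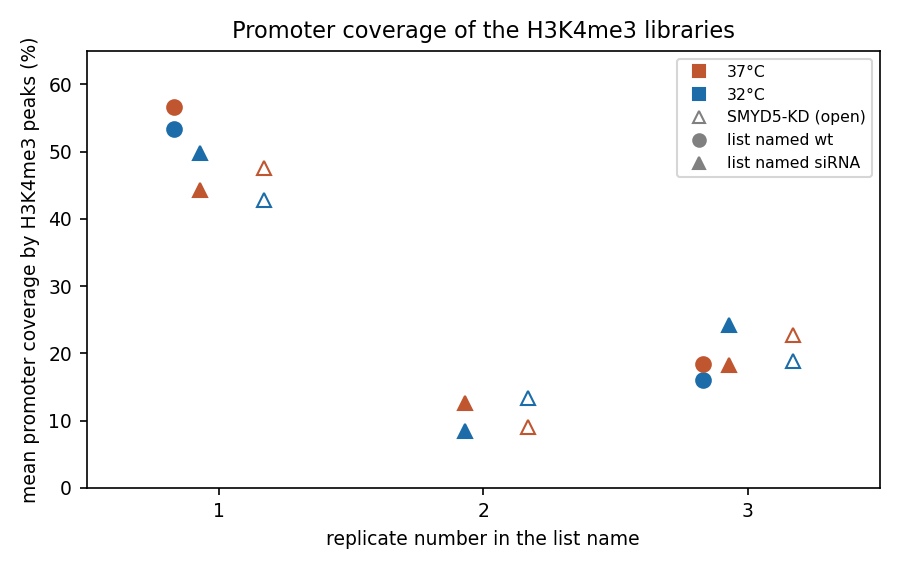
Mean promoter coverage by H3K4me3 peaks (percent, vertical axis) in each of 16 libraries, by the replicate number in the list name (horizontal axis). Colours give the temperature, open symbols SMYD5-KD, circles lists named wt and triangles siRNA-named lists. Libraries numbered 1 lie at 42.9% to 56.6% and all others at 8.44% to 24.2%.

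The temperature and knockdown effects at 37°C were also compared across genes, which are not independent replicates and share the 37°C libraries. For H3K36me3 the covariance was 20.7 and Pearson's r 0.441. Simulated unchanged groups, with residuals permuted over all libraries and a shared 37°C group, gave a covariance of 6.06 (SD 11.4). They were as large in 8 of 100 draws. With the 37°C libraries split between the comparisons, r was 0.0734 (from -0.243 to 0.286) and the covariance 3.45. For H3K4me3 the covariance was 78.6 and r 0.372, below the simulated covariance of 107 (SD 81.3; 63 of 100 as large), and r was -0.107 with the libraries split. Neither similarity lay beyond what this simulation of a shared 37°C group gave. It does not keep the real 37°C libraries, so it does not measure what those libraries themselves add. In lists of equal covered length the covariances were 39.2 and 212, for which no simulation was made.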

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

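Of 79 groups and measures tested for a library far from the others of its group, 4 were marked, and chance alone marks about 1 in 20. Only groups of at least 4 libraries were tested, so the SMYD5-KD groups (n = 3 each) were not. The tests of replicate 6 and of the list numbers given below were chosen after the result was seen.

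In H3K36me3 at 37°C, replicate 6 had 1.27% of its covered length in promoter windows, while the other 5 libraries had 0.636% to 0.838%. In the same group replicate 3 had 31.6% coverage over COXFA4, where the others had 0% to 9.06%, and 45.1% over CIAO1, where the others had 0% to 12.9%. In H3K4me3 at 37°C, replicate 5 had 6.27% of its covered length in promoter windows, against 12.1% to 14.4% in the other 4. Each was marked because a single library lay far from the rest.

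H3K36me3 replicate 6 at 37°C also had the lowest gene body share, 56.3% against 64.2% to 90.6%, and a mean correlation with the other H3K36me3 libraries of 0.365, where theirs were 0.714 to 0.844. A swap with an H3K4me3 library is argued against: its mean correlation with those was 0.116, lower by 0.249. Low enrichment, with peaks partly in background, has the value it needs, since 56.3% lies toward the 40.9% of randomly placed peaks, but a different state of that culture could look the same and was not tested. Without this library 166 of the 189 genes of the cold comparison were called again, which argues against it as their source.

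The H3K4me3 libraries of list number 1 had 42.9% to 56.6% mean promoter coverage, and the other 10 had 8.44% to 24.2%. Longer lists alone are argued against: at equal covered length number 1 remained higher by 7.86 points (exact permutation p = 0.00025, the smallest that test can give). That measure replaced an earlier one, the lowest library of number 1 minus the highest other, after its value was seen, and the bound of the next test was also made stricter after its values were seen. Peaks of the other numbers lying mostly in background stays open. Their median promoter share was 7.47 times that of random placement, but their gene body shares, 38.9% to 43.0%, lay around the random 40.9%. Number 1 had 54.5% to 57.8%. The promoter end of each gene was the end with the higher mean coverage over these same libraries, where number 1 had most. That choice can raise both the 7.86 points and the ratio of 7.47. A batch of preparation or sequencing may also be behind it, and as every number holds both temperatures and SMYD5-KD, no biological explanation was tested.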

How the results depend on the processing

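Across 23 results there were 377 alternative values, of which 284 kept direction and side of the threshold or stayed within 1.5 times, 75 moved and 18 reversed; the cause was not tested for any of them unless said. Array weights, list numbers 1 and 3 alone (cold without knockdown), leaving out the 2 least correlated libraries and a block by list number within batch were added after seeing the data. The number of genes called for H3K36me3 in the cold spanned 0 to 881, so it depends strongly on the setting. Depth is unknown, and 0 calls for H3K4me3 say little. Simulated changes of 30 points were found in 0.8% (cold) and 5.7% (knockdown at 37°C) on average over 5 runs, with 27.5% in the best run. The other comparisons and the block by list-name number were not simulated. Permuting over libraries can place the list numbers unevenly in the simulated groups, so these rates are a rough guide only. Of 500 values of the 20 genes that passed and that the naming rule selects, 311 kept the call, 189 lost it and 0 changed sign (the log2 scale and other window were compared by counts only). Of 2759 values of genes named as not passing, 146 changed sign and 158 passed. Within list number 2 no residual degrees of freedom were left, so no fit was made.

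H3K36me3 genes called in the cold without knockdown were 189, and 57 without the batch term, 122 without the covered-length term and 27 without both. They were 572 with quantile normalisation, 58 on the log2 scale, 75 with no filter and 32 in the other window. They were 0 in siRNA-named lists alone (SMYD5-KD included), 881 with array weights and 289 without the 2 least correlated libraries. Fits to only the libraries without knockdown of a single batch called 152 among siRNA-named lists and 343 among lists named wt. For cold in SMYD5-KD, knockdown at 37°C, knockdown at 32°C and the interaction (0 each), quantile normalisation gave 148, 322, 181 and 243, the log2 scale 98, 62, 60 and 83, and array weights 2092, 1405, 664 and 1099. Equal covered length gave 1 for cold in SMYD5-KD, 2 for knockdown at 32°C and 5 for the interaction; no filter gave 1 for cold in SMYD5-KD and 1 for knockdown at 37°C; leaving out the least correlated 2 gave 1, 6 and 21 for cold in SMYD5-KD, knockdown at 37°C and the interaction. Stricter peaks gave 3 for knockdown at 32°C and 7 for the interaction; siRNA-named lists alone gave 1, 9 and 3 for knockdown at 37°C, at 32°C and the interaction; the interaction was 2 without the covered-length term and 2 in the other window. The 8 H3K36me3 gene list calls became 0 with an estimated correlation, 0 with quantile normalisation, 0 at equal covered length and 1 in siRNA-named lists alone.

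H3K4me3 calls (0 throughout) for cold, cold in SMYD5-KD, knockdown at 37°C, at 32°C and the interaction became 77, 3125, 1923, 1350 and 1762 with array weights, and cold without knockdown 6 in list number 1 alone. The log2 scale gave 22, 25 and 2 for cold in SMYD5-KD and knockdown at 37°C and 32°C, and leaving out the batch term 2 for knockdown at 32°C and 2 gene lists. The covariance of cold and knockdown effects became 39.2 for H3K36me3 and 212 for H3K4me3 at equal covered length.

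Covered-length differences reversed to -0.0917 (H3K36me3 cold) and 0.0646 (H3K4me3 knockdown at 37°C) in siRNA-named lists alone. For H3K4me3 knockdown at 32°C they reversed to -0.10 with stricter peaks and -0.00951 for the number of peaks. Leaving out 1 library gave, for H3K36me3, 0.09 to 0.40 in the cold, -0.11 to 0.60 in the cold in SMYD5-KD, -0.89 to -0.18 for knockdown at 37°C and -0.77 to -0.36 at 32°C. For H3K4me3 it gave -0.12 to 0.70, -0.34 to 0.89, -0.46 to 0.66 and -0.38 to 0.65. Counts of genes ranged from 62 to 262 for H3K36me3 in the cold and 0 to 7 for its interaction, and for H3K4me3 0 to 4 for cold in SMYD5-KD, 0 to 2 for knockdown at 37°C and 0 to 2 at 32°C.

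A replicate block by label number, fitted without the batch term, changed the H3K36me3 counts to 49 for cold and 485 for cold in SMYD5-KD. It changed them to 377 for knockdown at 37°C and 233 at 32°C, and H3K4me3 knockdown at 32°C to 3555 (covered-length difference -0.24). In the H3K36me3 knockdown fits all not targeted lists were named wt and all SMYD5-KD lists were siRNA-named. Knockdown and batch thus cannot be told apart in those counts. All of these fits except H3K36me3 cold had 1 residual degree of freedom. In the cold the correlations of equally numbered H3K36me3 libraries ran from -0.15 to 0.75 and 4 of 6 correlated best with their own number, a hint from the data, so the numbers were not taken as pairs. A replicate block by list-name number in siRNA-named lists gave 0 for H3K36me3 cold, 1 for knockdown at 37°C, 14 at 32°C and 2 for the interaction. Where the numbers met the rule for pairing H3K4me3 libraries, the block changed no call.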

Other observations

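The tests of replicate 6 and of covered length and the splits within batches in this part were chosen after the result was seen; the free splits and the test between batches were planned.

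The genes called for H3K36me3 in the cold were short: the 147 that rose had a median length of 19030 bp and the 42 that fell 9853 bp, where all tested genes had 27672 bp.

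The 189 H3K36me3 calls in the cold, of which 166 were made again without 37°C replicate 6, were weighed against other sources. Of 100 splits of the 12 libraries 2 called at least as many, the real one and 1 other. Of 100 splits, from 200 possible, that keep 3 of each batch in each group 1 did, the real one (highest other 14). Other groupings of these libraries thus seldom gave as many calls, which makes chance less likely but does not exclude it. The free split with more calls, 973, joins 32°C replicates 1 to 4 with 37°C replicates 2 and 6 and points to a structure among the samples that does not follow the batch. The batch itself was also a strong structure: the same 12 libraries grouped by batch, in a fit without the batch term, gave 880 calls. Across the tested genes, the temperature differences fitted within each batch correlated with r = 0.277. Covered length stays open: in lists of equal length 97.4% kept their sign, which genes chosen in the same libraries would mostly do, and 34 of the 189 were called, with a median of 4.11 in place of 16.98 points, but shortening lowers all coverage (mean of the 12 libraries 11.8% to 4.69%), so neither value decides. Of 200 genes ranked in siRNA-named lists, 78.5% had the same sign in lists named wt, but another labelling gave 81.0%, so a difference made in 1 batch stays open, as does cold itself.

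For the other H3K36me3 comparisons the real count was 0, which every split reaches by construction, so relabelling says nothing about chance: 84 of 84 splits reached it for knockdown at 37°C (0 real, highest other 1812), 84 of 84 at 32°C (0, highest 2) and 100 of 100 for the interaction (0, highest 903). The split with 1812 calls joins SMYD5-KD replicate 1 with 37°C replicates 2 and 6, a structure of the samples. Cold in SMYD5-KD had too few splits (10 of 10; 0 real, highest other 0). The 8 H3K36me3 gene list calls were reached in 75 of 100 splits, the real one included (highest 35), so chance may explain them.

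For H3K4me3 the real counts were also 0 and the splits mix list numbers, so they say nothing about chance either: 0 was reached in 100 of 100 splits in the cold (0 real, highest other 71), 56 of 56 for knockdown at 37°C (0, highest 2), 56 of 56 at 32°C (0, highest 4679), 100 of 100 for the interaction (0, highest 5689) and 100 of 100 for gene lists (0, highest 9). Cold in SMYD5-KD had too few splits (10 of 10; 0 real, highest other 3). The split with 4679 calls is the one by list number 3, so this structure follows the list number.

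Array quality weights gave 37°C SMYD5-KD replicate 2 a weight of 13.3 for H3K36me3 and 26.2 for H3K4me3. With weights, relabelled splits called up to 2425 genes for the H3K36me3 cold comparison (881 real, 3 of 20 as large, the real one included) and up to 5783 for H3K4me3 (77 real, 12 of 20 as large), so the weighted counts were not used as results.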
